A study of Mus musculus with 2 samples.

How the data were processed

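H3K9me3 ChIP-seq was measured in 2 biological replicates of the mouse embryonic stem cell line E14TG2a.4, which form 1 group. The labels give each replicate its own biosample. No control library is in the series, and the labels only name a possible control experiment, which was not analysed here. The deposited files were peak lists, with no read counts or coverage, so depth is unknown.

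The fold enrichment of each peak, a linear ratio, was deposited by the authors, and what it is relative to is not given in the sources used here. In the mm10 lists, of narrowPeak type, the authors deposited −log10 p and −log10 q for each peak. In the mm9 lists, of broadPeak type, the deposited p-value and q-value were linear, all under 0.01, and all boundaries were multiples of 200 bp. Peak caller, aligner and their versions are not given in the sources used here. Per the deposited file lists, the pooled mm10 list was made from the alignments of both replicates, and the replicated mm10 list from the pooled and both per-sample lists. Whether the third mm9 list pools the replicates is not stated there, and it is called the pooled list here. Fold enrichments are the authors' values and were used only to describe, rank or filter peaks, so the mean ± SD of 2 replicates at a promoter describes values called separately in each list.

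Wide regions and narrow peaks affect measurements differently: a wide region reaches a promoter from further away, and narrow peaks break a block into pieces. The handling of reads that map to several places is not given in the sources used here, and it can add or remove signal at repeats.

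Overlap, chromosomes, windows and gene bodies were analysed in mm10 with the authors' replicated list and RefSeq gene positions of GRCm38.p6, which give no strand. Promoters, genic location and sequence needed strand, transcripts or sequence. These were given for mm9 only, so they were run on mm9 with GENCODE M1 (Ensembl 65), using the bases covered in both replicates. The fixed plan had left genic location and sequence out in this case. The change was made before any result was computed. The mm9 sequence was not soft-masked, so the share of bases starting a 16-mer present at least 50 times took the place of a repeat share. No coordinates were converted between builds. Chromosomes 1 to 19, X and Y were used, and peaks on unplaced scaffolds entered only the list lengths.

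In the rotation test all peaks of a chromosome were shifted together by 1 random distance, wrapping between its first and last peak, 1000 times with a fixed seed. Tests were 2-sided, as 2 times the smaller tail, except the 1-sided test of replicate overlap, and were adjusted by Benjamini-Hochberg over the 17 gene lists, the 4 genic classes or the 3 sequence measures. Rotation keeps the clustering of peaks but moves them between gene-rich and gene-poor sequence. A ratio to rotated peaks therefore includes any depletion at genes as a whole, and the set of all protein-coding genes sat below rotated peaks. A promoter was 1 kb either side of any transcript's start, and a gene counted when a shared region overlapped it by at least 1 bp. The 17 lists and the rule for named genes were fixed before the data were examined. The lists were zinc finger, SCAN domain, olfactory receptor, vomeronasal receptor, protocadherin, histone, ribosomal protein, Hox, cytochrome P450, imprinted, germ cell, 2-cell, pluripotency, lineage, fibroblast, H3K9 machinery and housekeeping genes. The rule named the 10 strongest protein-coding promoters, the 10 protein-coding genes of at least 5 kb with the most covered body, up to 4 of the strongest promoters per list, and up to 3 genes in each of the 5 densest windows. In a list with no marked promoter it named the first 2 members. On mm9 strength was the mean of the strongest overlapping region of each replicate.

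The list tests were checked on simulated region sets, rotated at random, with 20 draws and 199 rotations each. For promoters, over 37273 genes, 95% of lists of 30 genes raised 3-fold were called, 40% of those raised 2-fold, and 10% of unchanged lists. For gene bodies, over 49939 genes, 100% of lists of 30 genes raised 3-fold were called and 0% of unchanged lists. Lists of 30 genes or fewer can therefore miss a 2-fold difference. The simulated lists were called at an unadjusted p under 0.05, so the adjusted tests can call fewer. The simulated sets also had no depletion at genes, while all protein-coding promoters had a ratio of 0.360 in the data. The shares called therefore need not hold for the real lists.

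Alternatives were the pooled list, each replicate's own list, a −log10 q of at least 2, a fold enrichment of at least 4, peaks within 1 kb merged, promoter windows of 2.5 and 5 kb, the gene's 5′ end, Fisher's exact test, windows of 50 and 500 kb, and other overlap rules. Exact copies of 4 retroviral primer-binding sites were searched on both strands of mm9, with exact Clopper-Pearson intervals at 95%, which cover counting error only. Gene sequences were aligned to mm9 with minimap2 2.31-r1302. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9. With 2 replicates in 1 group, no comparison between conditions, outlier test or regrouping of samples was possible.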

Results

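The histone mark H3K9me3, trimethylation of lysine 9 of histone H3, was mapped by ChIP-seq in the mouse embryonic stem cell line E14TG2a.4. The line is male and derives from strain 129/Ola. H3K9me3 is a mark of silent chromatin, and in stem cells it is known at repeats and at imprinting control regions. The series holds 1 group of 2 biological replicates, from separate biosamples of the same line, and no second condition. The data were peak lists, so the read depth of each replicate is unknown. In mm10, replicate 1 had 161565 peaks covering 69.8 Mb and replicate 2 had 198948 peaks covering 100.6 Mb. The authors' replicated mm10 list had 123489 peaks covering 93.2 Mb. In mm9, where regions were wider, replicate 1 had 43006 regions covering 222.0 Mb and replicate 2 had 53405 covering 256.1 Mb. The 2 replicates shared 195.9 Mb of mm9 sequence, called shared regions here.

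H3K9me3 lay at the promoters of imprinted genes far more often than rotated regions did. Of 28 imprinted genes or genes at imprinting control regions, 19 had a shared region within 1 kb of a transcription start site in mm9, which is 67.9%. Rotated regions reached 19.7% of them on average, a ratio of 3.44. The strongest was Nnat, which encodes neuronatin, at a fold enrichment of 11.4 ± 1.53 (SD, n = 2). The noncoding RNA gene H19 had 7.70 ± 1.84, the zinc finger gene Plagl1 had 6.86 ± 1.87 and Mest had 6.72 ± 1.71. Also covered were Gnas and Nespas, Peg10 and Sgce, Peg3, Snrpn, Meg3, Airn, Igf2r, Grb10, Nap1l5, Inpp5f, Impact, Mcts2 and Zrsr1. These further names lie outside the rule for named genes and were chosen after their values were seen. Gnas and Nespas had the same fold enrichment, 6.33 ± 1.52, as did Peg10 and Sgce, 4.88 ± 2.48, so the 19 genes are not all independent. Cdkn1c, Dlk1, Magel2, Ndn, Rasgrf1, Slc38a4, Usp29, Zdbf2 and Zim1 had no shared region at the promoter. The 2-sided rotation test gave an adjusted p of 0.0113 over the 17 gene lists. The unadjusted p of 0.002 is the smallest that 1000 rotations can give.

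Promoters of ribosomal protein genes, which are active in every cell, and of olfactory receptors carried the mark less often than rotated regions did. Of 78 ribosomal protein genes, 2 had a shared region, against 13.1% with rotated regions, a ratio of 0.196. This low share did not pass by Fisher's exact test (odds ratio 0.448, adjusted p 0.555) or at a fold enrichment of at least 4 (adjusted p 0.467), where adjusted p ranged from 0.0113 to 0.555 over the alternatives. The 2 genes were Rpl7a, at a fold enrichment of 2.97 ± 1.102 (SD, n = 2), and Rps15a, at 2.09 ± 0.67. Of 1087 olfactory receptor genes, 42 or 3.86% had one, against 10.8%, a ratio of 0.358. Among these 42 the strongest were Olfr1155 at 9.43 ± 1.17, Olfr1055 at 9.39 ± 2.19, Olfr784 at 8.27 ± 0.98 and Olfr292 at 7.07 ± 1.70. Both lists had an adjusted p of 0.0113. The low olfactory receptor share depended on the window: at 5 kb either side of the start site the ratio was 1.104, with an adjusted p of 0.573, the highest of a range from 0.0113 over the alternatives. Olfactory receptors also missed the threshold at 2.5 kb and at a fold enrichment of at least 4. The background is itself low, since 1239 of 22367 protein-coding genes, 5.54%, had a shared region at a promoter, against 15.4% with rotated regions. That is a ratio of 0.360, close to that of olfactory receptors. Against other protein-coding genes, Fisher's exact test gave olfactory receptors an odds ratio of 0.674 with an adjusted p of 0.0400.

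The other 14 lists did not pass the rotation test. Of 365 genes with a zinc finger protein symbol, 44 or 12.1% had a shared region, against 15.3% with rotated regions, a ratio of 0.788 and an adjusted p of 0.290. Zfp385c had a fold enrichment of 11.7 ± 3.08 (SD, n = 2), Zfp629 11.2 ± 2.90, Zfp575 9.79 ± 2.51 and Zfp553 8.10 ± 1.14. Against all other protein-coding genes, Fisher's exact test, which treats genes as independent, gave this list an odds ratio of 2.39 with an adjusted p of 1.09e-05. That excess lay in promoters rich in high-copy sequence. The 213 with a high-copy share at or above the median of protein-coding promoters had an odds ratio of 3.66, the 152 below it 0.822. Of 91 cytochrome P450 genes, which encode enzymes of drug and steroid metabolism, 18 or 19.8% had a region, with a ratio of 1.63 and an adjusted p of 0.187. At 5 kb either side of the start site this list passed, with a ratio of 1.68 and an adjusted p of 0.0476, the lowest of a range up to 1 over the rotation alternatives. Their strongest members were Cyp4a32 at 5.98 ± 1.24, Cyp2b23 at 4.87 ± 0.96, Cyp2c69 at 4.46 ± 1.47 and Cyp2c67 at 4.39 ± 1.32. Of 31 germ cell genes 8 had a region, with a ratio of 1.68 and an adjusted p of 0.290. They included Zcwpw1 at 6.70 ± 2.07, Dpep3 at 5.06 ± 1.59, Slc25a31 at 4.88 ± 3.18 and the bromodomain gene Brdt at 3.08 ± 1.03. Fisher's exact test gave the P450 list an odds ratio of 4.25 and the germ cell list 5.96, with adjusted p of 1.21e-05 and 0.000925.

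**Figure D1:**
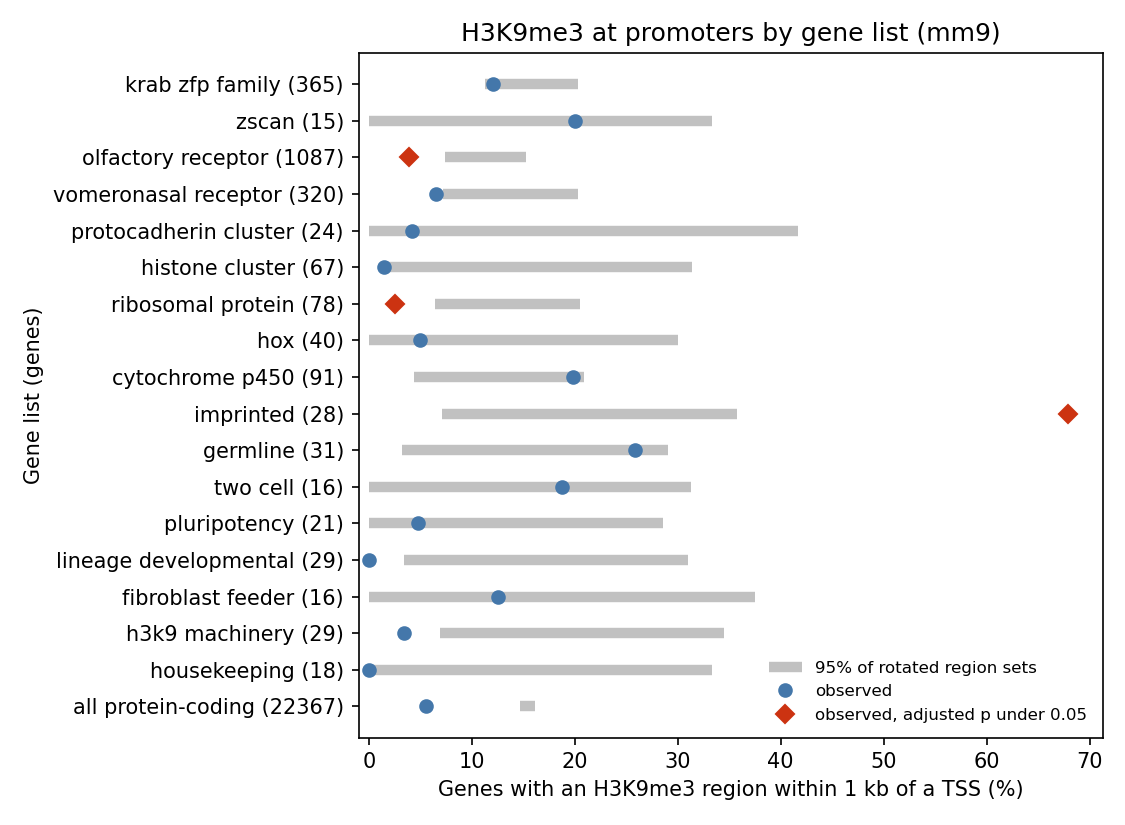
Percent of each list's genes, with the number of genes in brackets, that had an H3K9me3 region shared by both replicates within 1 kb of a transcription start site in mm9. Grey bars span 95% of rotated region sets, and diamonds mark the 3 lists with an adjusted p under 0.05, of which the imprinted genes lie above their bar at 67.9% and the olfactory receptor and ribosomal protein genes below theirs.

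Markers of the stem cell, of other cell types and of the H3K9 machinery were mostly free of the mark at promoters, like protein-coding genes in general. Of all protein-coding genes 5.54% had a region. Fisher's exact test against other protein-coding genes gave none of these lists an adjusted p under 0.05. Of 21 pluripotency genes 1 had a region, Dppa3, an imprinting protector of the early embryo, at 6.14 ± 1.58 (SD, n = 2). None of 29 regulators of differentiated lineages had one, Gata4 and Gata6 among them, against 15.3% with rotated regions and an adjusted p of 0.0679, which ranged from 0.0170 to 1 over the rotation alternatives. None of 18 housekeeping genes had one, including Actb and Gapdh, with an adjusted p of 0.155. Of 16 fibroblast genes, which feeder cells would express, 2 had a region, Lum at 4.91 ± 0.05 and S100a4 at 2.59 ± 0.50, with an adjusted p of 1. Of 29 gene entries for writers, readers and erasers of H3K9 methylation 1 had a region, with an adjusted p of 0.0679. It was Atf7ip, a partner of the H3K9 methyltransferase Setdb1, at 4.63 ± 1.08, and a second annotated entry with that symbol had none. Hoxd12 at 7.65 ± 1.19 and Hoxb3 at 2.22 ± 0.06 were the 2 of 40 Hox genes, with an adjusted p of 0.533. The entry named Pcdha11 at 7.74 ± 1.76 was the 1 of 24 clustered protocadherin genes, and Hist1h2al at 2.94 ± 0.53 the 1 of 67 histone genes, with adjusted p of 0.548 and 0.211. In mm9 the Pcdha11 entry runs from 37089939 to 37347311, longer than its 176.8 kb in mm10, and any of its transcript starts counted. The marked start site may therefore belong to another gene of the cluster. The protocadherin list held 57 genes in mm10.

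Of 320 vomeronasal receptor genes 21 had a region, with a ratio of 0.531 and an adjusted p of 0.0793. The strongest were Vmn1r45 at 6.90 ± 2.19 (SD, n = 2), Vmn2r104 at 6.80 ± 1.73, Vmn2r82 at 5.49 ± 0.78 and Vmn2r22 at 4.66 ± 1.58. Of 15 SCAN domain zinc finger genes 3 had one, Zscan4b at 4.64 ± 3.20, Zscan4e at 3.82 ± 1.93 and Zscan30 at 3.52 ± 1.94, with an adjusted p of 0.860. Of 16 genes of the early 2-cell embryo 3 had one, Zscan4b, Zscan4e and Tdpoz3, the last at 3.94 ± 0.85, with an adjusted p of 0.788.

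The strongest promoter regions of protein-coding genes belonged to genes of no single list. Efnb1, which encodes the signalling ligand ephrin B1, lies on X from 96331469 to 96344330 in mm9 and had a fold enrichment of 17.5 ± 4.72 (SD, n = 2). Strc, which encodes stereocilin of the inner ear, lies on chromosome 2 from 121189464 to 121212904 and had 14.8 ± 4.80. Nipal3 on chromosome 4 had 12.5 ± 3.48, Polrmt, the mitochondrial RNA polymerase, had 12.1 ± 2.28, and Pld1, a phospholipase, had 11.8 ± 3.63. The predicted genes Gm7735, Gm17579, Gm10061 and Gm17558 had 12.8 ± 3.50, 12.6 ± 3.32, 12.5 ± 3.73 and 11.98 ± 3.21. Replicate 2 had the higher value at each of these 9 promoters. Promoters were not measured in mm10, where only gene bodies were available. Replicated mm10 peaks covered 71.9% of the Polrmt gene body, 12.5% of Efnb1, 0.912% of Pld1, and 0% of Strc, Nipal3, Gm7735 and Gm10061. The bodies of Gm7735 and Gm10061 are only 0.159 and 0.165 kb long, so their 0% says little about the promoter window.

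Some gene bodies were covered almost end to end by replicated mm10 peaks. Prmt5, which encodes an arginine methyltransferase and lies on chromosome 14 from 54507182 to 54517470, was covered over 95.9% of its 10.3 kb, with 94.3% in replicate 1 and 96.0% in replicate 2. Haus4, a subunit of a spindle complex, lies nearby from 54541785 to 54554989 and was covered over 93.1%. Zfp629 on chromosome 7 reached 93.4%, Eif3f, a translation initiation factor subunit, 93.2%, and Blcap on chromosome 2 91.7%. Tmppe reached 91.3%, D10Wsu102e 88.8%, the neurofilament gene Nefm 87.7%, the cytokine receptor gene Il3ra 85.9% and B230307C23Rik 84.9%. Nnat, which lies within Blcap, was covered over 100% of its 2.45 kb. Replicate 1 covered 71.1% of B230307C23Rik and at least 81.6% of the other 9 genes.

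**Figure D2:**
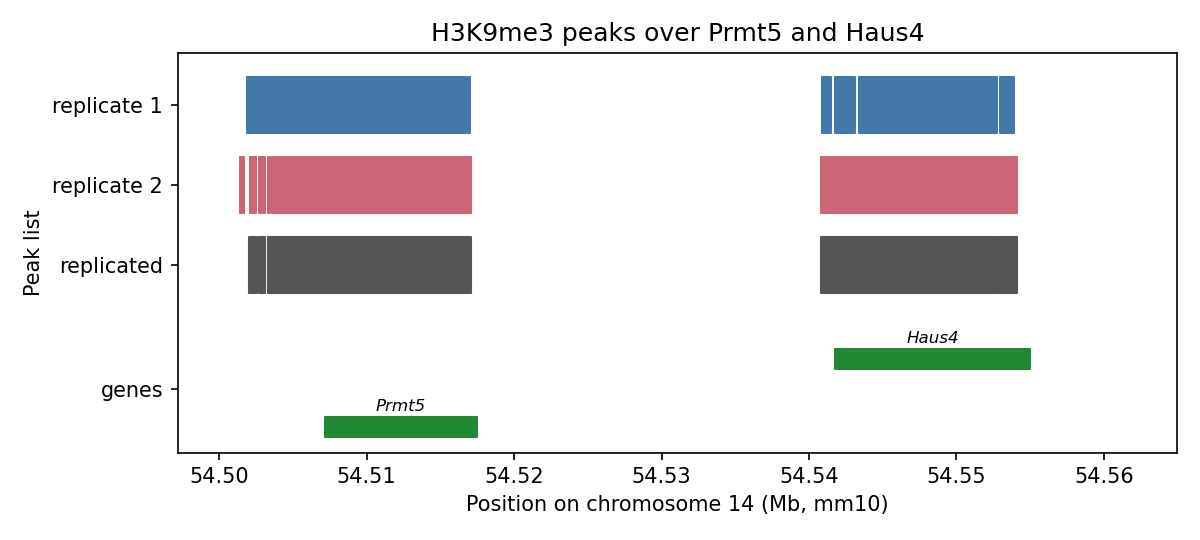
Peaks of each replicate and of the replicated list (blocks, upper tracks) and protein-coding genes (green) on chromosome 14 in mm10, with position in Mb on the horizontal axis. Blocks in both replicates lie over most of Prmt5, covered over 95.9% by replicated peaks, and of Haus4, covered over 93.1%. The replicated peaks end at 54517050 and 54554131, before the genes end at 54517470 and 54554989. Both genes are on the minus strand in the mm9 annotation, so the uncovered end is the side of the start site.

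Over gene bodies in mm10 no gene list passed the rotation test. Protein-coding gene bodies as a whole were covered over 2.27% in mm10, against 3.65% with rotated peaks, a ratio of 0.623. No list of the 17 passed after Benjamini-Hochberg adjustment in the rotation test, and 2 lists had an unadjusted p under 0.05. Imprinted gene bodies were covered over 8.46%, against 3.99%, with an unadjusted p of 0.0300 and an adjusted p of 0.255. The bodies of H3K9 machinery genes were covered over 1.24%, against 3.44%, with an unadjusted p of 0.00400 and an adjusted p of 0.0679. Zinc finger gene bodies were covered over 4.62%, against 3.80%, with an adjusted p of 0.641. With mm9 shared regions and GENCODE genes, 4 lists were lower than rotated regions. These were ribosomal protein, lineage, H3K9 machinery and housekeeping genes. Protein-coding gene bodies as a whole were themselves low in that setting, at 3.61%, against 7.51%, a ratio of 0.480. Zinc finger gene bodies turned from a ratio of 1.22 in mm10 to 0.815 there.

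H3K9me3 lay mostly outside protein-coding genes. The promoter, exon and intron classes were those of protein-coding genes only, so sequence called intergenic here includes all other genes. Of the bases in shared mm9 regions, 81.4% were intergenic, against 61.2% with rotated regions, a ratio of 1.33. Introns held 17.05%, against 33.6%, exons 0.694%, against 2.22%, and promoters 0.815%, against 3.01%. The ratio was 0.270 for promoters and 0.313 for exons, and with promoters of 2.5 kb either side 0.316 and 0.311. All 4 classes had an adjusted p of 0.002 in the 2-sided rotation test, which is the smallest that 1000 rotations can give.

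The marked sequence was rich in high-copy sequence and in CpG. Of the bases in shared mm9 regions, 51.4% began a 16-mer found at least 50 times in the genome, against 18.9% with rotated regions. CpG density was 10.6 per kb, against 8.29, and 14.5 per kb in regions with a fold enrichment of at least 4 in both replicates. GC content was 42.4%, against 41.7%. All 3 measures had an adjusted p of 0.002 in the 2-sided rotation test, the smallest it can give.

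Coverage differed between chromosomes. Replicated mm10 peaks covered 3.50% of the chromosomes' spans. Chromosome 17 had the highest coverage at 4.62%, a ratio of 1.32 to the genome, with 1.36 in replicate 1 and 1.28 in replicate 2. Chromosome 13 had a ratio of 1.26, with 1.27 and 1.24, and chromosome 19 had 0.762, with 0.703 and 0.791. X had 1.41% of its span covered, a ratio of 0.403, with 0.330 in replicate 1 and 0.471 in replicate 2. Y had a ratio of 0.0481. In mm9 the order of the chromosomes differed: shared regions gave X a ratio of 1.12 and Y 3.01, and chromosome 17, at 1.103, lay below chromosomes 7, 13 and 3, at 1.23, 1.16 and 1.12. The mm9 ratio of Y rests on a span of only 2.69 Mb. With 2 replicates of 1 group no test was made.

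**Figure D3:**
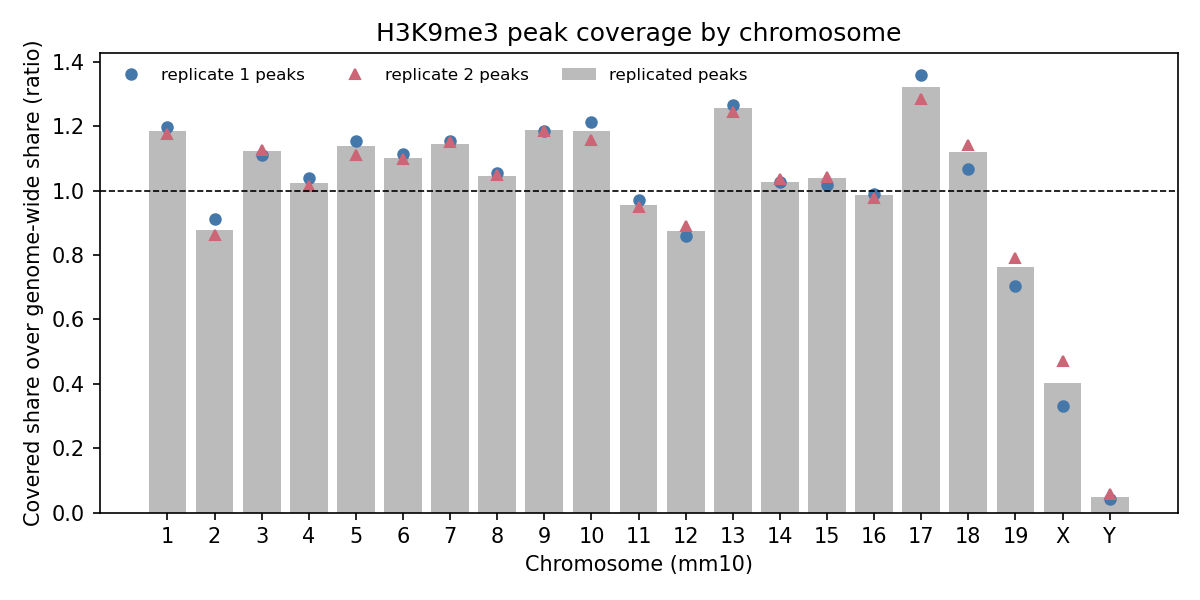
Share of each mm10 chromosome's span covered by peaks, divided by the genome-wide share, for the replicated list (bars), replicate 1 (circles) and replicate 2 (triangles), with a dashed line at a ratio of 1. Chromosome 17 is highest at 1.32 and X, at 0.403, lies below each autosome in all 3 lists.

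In mm10, replicated peaks rarely covered most of a window of 100 kb. Windows were not counted in mm9, where the widest region was 140200 bp in replicate 1 and 112400 bp in replicate 2. The counts therefore hold for the narrow mm10 peaks only. Of 27235 such windows in mm10, 8 were at least 50% covered and 5796 had no replicated peak. The 8 became 4 without replicate 2, 8 without replicate 1, 13 with the pooled list and 20 with peaks merged, and depended most on window size, with 45 at 50 kb and 0 at 500 kb. The densest lay on chromosome 18 from 36800001 to 36900000, with 69.0% covered, 55.5% in replicate 1 and 70.6% in replicate 2, and held the vault RNA gene Vaultrc5. A window on chromosome 10 from 83400001 to 83500000, with Gm8270, Aldh1l2 and Gm51778, was covered over 66.7%. Further windows lay on chromosome 18 from 74300001, with Cfap53, at 62.1%, and on chromosome 17 from 27200001, with Lemd2, a nuclear envelope gene, at 60.9%. The fifth lay on chromosome 16 from 98000001, with C030010L15Rik, B230307C23Rik and Vmn2r-ps112, at 60.0%.

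The replicates shared strong peaks more often than weak ones. In mm10, 76.1% of replicate 1 peaks were overlapped by a replicate 2 peak by at least 1 bp, against 6.56% with rotated peaks. Of replicate 2 peaks 53.3% were overlapped, against 5.23%. The Jaccard index of covered bases was 0.479, against 0.0169. Each of the 3 values had a 1-sided rotation p of 0.001, the smallest that 1000 rotations can give. With each list split into 4 equal parts by −log10 p, the strongest part had 99.2% of replicate 1 peaks and 93.9% of replicate 2 peaks overlapped, and the weakest part 50.2% and 24.8%. Across 97282 replicated peaks overlapped in both replicates, fold enrichments had a Spearman correlation of 0.656 and a Pearson correlation of 0.796, and peaks are not independent replicates. Replicate 2 had the higher fold enrichment at 80.2% of them.

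**Figure D4:**
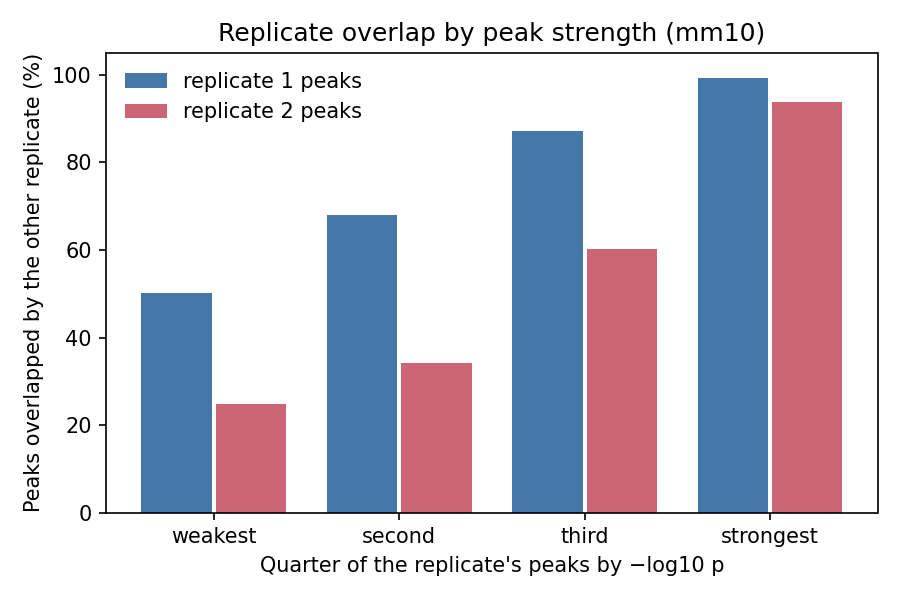
Percent of each replicate's mm10 peaks overlapped by at least 1 bp by a peak of the other replicate (vertical axis), for 4 equal parts of its peaks ranked by −log10 p (horizontal axis). The share rises from 50.2% to 99.2% in replicate 1 and from 24.8% to 93.9% in replicate 2.

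The replicated list was a part of the authors' pooled list, since all 123489 of its peaks were identical to a pooled peak. Of these, 97425 or 78.9% were overlapped by peaks of both replicates, 21443 by replicate 2 only, 3997 by replicate 1 only and 624 by neither. The median fold enrichment was 4.65 for those overlapped by both and 3.30 for the rest. The mm9 and mm10 lists of the same libraries differed in width. The median width was 4000 bp in mm9 and 289 bp in mm10 for replicate 1, and 3600 bp and 310 bp for replicate 2. Covered sequence in mm9 was 3.18 times that in mm10 for replicate 1, 2.55 times for replicate 2 and 2.44 times for the pooled list.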

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

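The mm10 lists held peaks on scaffolds that are not placed on a chromosome, which no comparison used. The replicated list had 180 such peaks on 27 scaffolds, above the limit of 3 that a count of 0 allows. Replicate 1 had 223, replicate 2 had 299 and the pooled list had 294. The mm9 lists had 0. No biological explanation was tested.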

How the results depend on the processing

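Alternatives were fixed before the data were examined, except the mm9 gene bodies and the peaks called in both replicates, which were chosen after seeing the files. A −log10 q of at least 2 removed no mm9 region and gave no separate value there. Replicate overlap, genic location and sequence composition kept their direction and side of the threshold in each alternative run. The imprinted promoters did too, with ratios from 2.05 at 5 kb to 4.98 at a fold enrichment of at least 4, and an odds ratio of 36.4 by Fisher's exact test. The cause of the differences was not tested. The replicated set of 123309 peaks on chromosomes became 203469 with the pooled list, 69616 at a fold enrichment of at least 4 and 73111 when merged. The Spearman correlation was 0.697 for −log10 p. The 3 promoter lists past the threshold became 5 with the pooled list, 5 at 5 kb, 5 by Fisher's exact test and 1 at a fold enrichment of at least 4, and 4 to 5 with 1 replicate left out. Lineage genes passed with the pooled list, with either replicate left out, and at 2.5 and 5 kb. H3K9 machinery genes passed with the pooled list and without replicate 2, and P450 and housekeeping genes at 5 kb. Body lists past the threshold went from 0 to 4 with mm9 regions and GENCODE genes together. The densest window went from 69.0% to 80.5% when merged, 77.9% at 50 kb, 35.8% at 500 kb, and 59.7% to 70.6% with 1 replicate left out. The covered mm9 to mm10 ratio of the pooled list was 1.94 when merged, and 2.42 and 1.98 for replicates 1 and 2.

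Olfactory receptor promoters missed the threshold at a fold enrichment of at least 4 (ratio 0.439) and at 2.5 kb (0.676), and turned to 1.104 at 5 kb. Ribosomal protein promoters missed it at a fold enrichment of at least 4 (0) and by Fisher's exact test (odds ratio 0.448). Lists that had not passed changed direction as follows. At a fold enrichment of at least 4, promoter ratios were 1.02 for zinc finger, 0 for SCAN domain, 1.16 for protocadherin, 0.742 for germ cell, 0 for 2-cell, 1.23 for pluripotency and 1.49 for fibroblast genes. By Fisher's exact test odds ratios were 2.39 for zinc finger, 1.201 for vomeronasal receptor and 2.44 for fibroblast genes. Vomeronasal receptors had 1.103 at 2.5 kb and 1.43 at 5 kb. Fibroblast genes had 1.12 at 5 kb, 1.22 for the 5′ end, and 0.624 to 1.07 with 1 replicate left out, the higher without replicate 2. Over gene bodies, mm9 regions and GENCODE genes gave 0.815 for zinc finger, 1.37 for vomeronasal receptor, 0.139 for Hox and 1.40 for 2-cell genes. Hox genes had 0.170 at a fold enrichment of at least 4 and 0.943 with peaks called in both replicates. Ribosomal protein bodies had 1.01 at a fold enrichment of at least 4, and 0.730 to 1.02 with 1 replicate left out, the higher without replicate 1. Of the other values of single lists, genes and chromosomes, 558 kept direction and side of the threshold or, where no test was made, stayed within the replicate spread. A further 15 moved past the threshold and 16 moved by more than the replicate spread, 14 of them down.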

Other observations

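Retroviral primer-binding sites, where a transfer RNA primes reverse transcription, mostly lay in H3K9me3. Of 1065 exact copies of the phenylalanine site TGGTGCCGAAACCCGGGA in mm9, 1016 or 95.4% lay in regions shared by both replicates (exact 95% interval 94.0% to 96.6%). The proline site TGGGGGCTCGTCCGGGAT had 117 of 146 copies in shared regions, 80.1%. The lysine sites TGGCGCCCAACGTGGGGC and TGGCGCCCGAACAGGGAC had 57 of 64 and 48 of 60, 89.1% and 80.0%. Replicate 1 held 95.8% of the phenylalanine copies and replicate 2 96.1%. Of the 201 copies inside protein-coding genes 96.5% lay in shared regions, and of the 864 outside 95.1%. In regions with a fold enrichment of at least 4 in both replicates, the shares were 84.5% for the phenylalanine, 67.8% for the proline, and 34.4% and 31.7% for the lysine sites. The reversed sites had 0 copies.

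Tests of the gene bodies and of X were chosen after those patterns had been seen. The mm9 coverage of the gene bodies, its comparison with random genes and the list lengths at stricter thresholds were tested after those values had been seen. The count of peaks at a −log10 q under 2 was also chosen after the values had been seen. The other tests were set down before the results. For primer-binding sites, the share of phenylalanine copies was 12.4 times that with rotated regions, with a 2-sided rotation p of 0.002, the smallest it can give. That met the bound set down for H3K9me3 at endogenous retroviruses, which stays a candidate explanation. The ratio measures the pattern itself, so it is no separate support for this explanation. Calling of any high-copy sequence is argued against, since random loci matched on high-copy share lay in regions 0.323 times as often. Reads that map to many copies stay open, as their handling is not given in the sources used here. The design has no second condition, so no biological explanation was tested between groups.

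Prmt5, Eif3f, Haus4 and other gene bodies that mm10 peaks covered almost entirely form a second pattern. Reads from a second copy in the assembly are argued against for the set, since 1 of the 9 genes found in GENCODE M1 had another alignment in mm9 over at least 50% of its length, against 10 of 100 random genes. That gene was B230307C23Rik, for which such reads stay open, and Tmppe, absent from GENCODE M1, was not searched. Of the 9 genes, 6 were at least 50% covered by shared mm9 regions. That count lay between the bounds set for the mm10 peak caller, so it could not decide. Of 100 random genes 4 were so covered (p 7.86e-06, Fisher's exact test). The test treats genes as independent, though Prmt5 and Haus4 lie near each other. With that limit, the comparison with random genes argues against the mm10 peak caller as the whole cause. It stays open for D10Wsu102e, at 0%, for B230307C23Rik, at 97.5% in replicate 1 and 0% in replicate 2, and for Nefm, at 33.4% of an mm9 body of 42.3 kb that is not comparable with its 5.46 kb in mm10, and neither extra copies in strain 129/Ola nor a biological explanation was tested.

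X was less covered than the autosomes in mm10, at 0.488 times their peaks per Mb, but not in mm9, at 1.205 and 1.17 times for the replicates. The test of 1 X copy per cell assumed fold enrichments relative to a genome-wide background, lowered on X with copy number. X peaks at a fold enrichment of at least 3 would then have been about as dense as autosomal peaks at 6 or more. The ratio was 1.87 in the replicated list, between the bounds set for it, and 11.5 and 7.55 in mm9. In the mm10 replicates it was 2.88 and 2.41, above the bound of 2 set to argue against 1 X copy under that assumption. What the fold enrichment is relative to is not given, so these ratios cannot decide on copy number. Median fold enrichments were equal on X and autosomes in each mm10 replicate, at 3.38 and 3.83, which the calling threshold could also give. High-copy sequence made up 1.28 times as large a share of mm9 regions on X, between the bounds but below the 1.51 of X as a whole, and the 2 explanations cannot be told apart, since the mm9 and mm10 lists differ in build and in width together, and no biological explanation was tested.

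Other tests were set down for a share of zinc finger promoters above rotated regions. That share was not found, while Fisher's exact test against other protein-coding genes gave an odds ratio of 2.39. The bounds set down for these tests did not ask for such a share, and no verdict was drawn from them. The 152 zinc finger promoters low in high-copy sequence had a ratio to rotated regions of 0.330 and an odds ratio of 0.822, the 213 others had 1.07 and 3.66, and the ratio over gene bodies in mm10 was 1.22. The longer mm10 list of replicate 2 had 23124 peaks at a −log10 q under 2, against 41395 in replicate 1. Such peaks therefore did not supply its surplus. The lowest −log10 q was 0.633 in replicate 2 and 0.473 in replicate 1, so this cutoff is not equally near the threshold in both. Replicate 2 peaks that replicate 1 did not overlap had a median fold enrichment of 3.28, against 4.92 for the others. Whether weaker calls make up the surplus stays open. The ratio of list lengths was 1.23 as deposited, 1.46 at a −log10 q of at least 2 and 1.78 at a fold enrichment of at least 4. The overlap test set down for weak calls met its bounds, with 93.9% of the strongest and 24.8% of the weakest of 4 equal parts overlapped by replicate 1, but strong peaks overlapped more often than weak ones in replicate 1 too, so it does not speak to list length.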
